A study of Rattus norvegicus with 24 samples.

How the data were processed

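Neonatal rat striatal neurons were cultured to day 7 and treated with combinations of the D1 receptor agonist SKF, a bromodomain inhibitor (JQ1 or iBD2) and DMSO, per the labels. Total RNA was extracted with a column kit and made into stranded libraries after removal of ribosomal RNA, per the labels. The labels give no doses. They name 24 samples in 12 groups over 3 experiments, and 23 libraries were analysed here. Replicate 2 of SKF plus iBD2 is not analysed here. The authors used Trim Galore, FastQC, STAR, StringTie and DESeq2 with the rat genome build Rnor_6.0, per the submitters' processing notes, which give no versions. All coordinates are those of the files.

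Each deposited file is a StringTie table of 41078 transcripts of 32883 genes, 32851 of them with a gene name, with the FPKM of each transcript (fragments per kilobase of transcript, scaled to the aligned fragments of the library) as computed by the authors. The deposited files also hold coverage, the mean number of reads over each base of a transcript, as computed by the authors. Whether the counting used the strand of the reads is not given in the sources used here, so overlapping and antisense genes are uncertain. Coverage multiplied by length peaked at 101 and 202 bases for transcripts with little signal, the length of 1 read and of a pair. From coverage and FPKM, the aligned bases came to 7.23 to 11.4 gigabases per library in experiment 1, 4.36 to 7.20 in experiment 2 and 6.48 to 14.9 in experiment 3. Transcripts held 79.5 to 81.3% of these bases. Mitochondrially encoded genes took 9.91 to 12.2% in experiment 1, 6.57 to 7.38% in experiment 2 and 10.6 to 13.3% in experiment 3. FPKM are not counts, so no count model was used for the main tests.

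Gene FPKM were summed over transcripts, divided by a median-ratio size factor per library (0.95 to 1.07) and taken as log2(FPKM + 0.5). Fold changes on this scale understate the change of low genes. Genes needed an FPKM of at least 0.5 in at least 2 libraries and a longest transcript of at least 200 nucleotides, which left 13999 genes. A linear model with 1 mean per group was fitted to all 23 libraries with limma 3.58.1 in R 4.3.3 (trend and robust options, 11 residual degrees of freedom), so that groups of 2 share an estimate of the spread. The lone SKF plus iBD2 library is assumed to vary like the other groups. All 15 comparisons are contrasts of that model, tested on both sides, and an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested) was the threshold for a call. An interaction is the SKF effect with inhibitor minus the SKF effect without it. Differences between inhibitors or times compare effects across experiments, each relative to the DMSO group of its own experiment.

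Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 315 tests of 21 lists. Of these, 100 had an adjusted p under 0.05 at the preset correlation and 15 with the estimated one. The lists were immediate early genes, later activity and cAMP response genes, striatal projection neuron genes, glutamate receptor and synapse genes, ion channels, BET and P-TEFb genes, reported BET inhibitor markers, histone, ribosomal protein, respiratory chain and mitochondrially encoded genes, cholesterol synthesis, inflammatory and NF-kB, interferon response, stress, cell cycle, and matrix and fibroblast genes, and markers of astrocytes, oligodendrocytes, microglia, and excitatory neurons and interneurons. Of the endothelial and mural list 2 of 16 genes were tested, too few for a list test. Some genes are in more than 1 list. Symbols were matched to those of the files, 3 of them through synonyms of a RefSeq gene table. SKF-induced sets were the genes that rose with SKF in experiment 2, tested in experiment 1, and the reverse.

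The comparisons, the main model, the lists, the alternatives and the rule for named genes were chosen before the data were examined. By that rule a comparison names the largest 10 rises and 10 falls in order, or the first of them, among called genes with a symbol, a mean FPKM of at least 1 in the higher group and, except for differences of effects, no overlap between the libraries of the groups within an experiment. It also names up to 4 members of each list by smallest p, and Fos, Fosb, Egr1, Arc, Npas4, Nr4a1, Bdnf, Drd1, Drd2, Ppp1r1b, Hexim1, Myc and Brd3 anywhere. Some genes this rule takes are not reported here. Ltc4s, AABR07017159.1, AABR07072184.1 and the hypoxia genes were named after their values were seen. The alternatives were FPKM as deposited, pseudocounts of 0.1 and 1, no filter on low values, the replicate number as a block, each experiment fitted alone, limma voom on reads estimated from coverage, and each library left out in turn. In these alternatives a list or set call was judged by an unadjusted camera p under 0.05 at the preset correlation. That rule is looser than the adjusted p of the main list tests. Tables were prepared in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

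The code was tested on simulated data with 200 of 13999 genes changed by 1.5-, 2- or 3-fold. For SKF at 60 min 98.5, 100 and 100% of them were recovered, with 10 false calls. For JQ1 at 60 min 91.0, 100 and 98.5% were recovered, with 12 false calls. For the SKF by JQ1 difference 82.1, 98.5 and 98.5% were recovered, with 10 false calls. For iBD2 with SKF, where a group has 1 library, 91.0, 98.5 and 98.5% were recovered, with 4 false calls. Simulated data cannot show whether the real SKF plus iBD2 library varies like the other groups, so that assumption stays untested. Recovery was summarised by fold and not by expression level, so these percentages may not hold for low genes. In 3 sets, 6 genes in all had identical values in every library and share their reads.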

Results

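RNA was sequenced from primary neurons cultured from the striatum of neonatal rats and treated on day 7 in culture. The striatum is the part of the forebrain that receives most of the dopamine input, and its projection neurons carry either the D1 or the D2 dopamine receptor. The series crossed SKF, an agonist of the D1 receptor, with an inhibitor of bromodomains, the modules by which BRD proteins bind acetylated histones. Experiment 1 used the BET family inhibitor JQ1 for 60 min, experiment 2 used the inhibitor named iBD2 for 60 min, and experiment 3 used JQ1 for 24 h. Each experiment had DMSO, SKF, inhibitor, and SKF plus inhibitor groups, with 2 libraries in each of the 12 groups except SKF plus iBD2, of which 1 library was analysed here. Aligned bases, computed from coverage and FPKM, came to 4.36 to 14.9 gigabases per library. The labels do not state that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Values below are means with SD (n = 2) in FPKM, or log2 fold changes ± SE from limma, with Benjamini-Hochberg adjusted p.

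The first question was which genes D1 receptor stimulation moves within 60 min. Immediate early genes, which neurons transcribe within minutes of activity, rose most. Nr4a2, an orphan nuclear receptor (chromosome 3, 43111240 to 43119159), went from 5.1 ± 0.694 to 34.2 ± 3.99 FPKM in experiment 1 and from 3.49 ± 0.219 to 37.8 ± 1.34 FPKM in experiment 2. Over both experiments its log2 fold change was 2.98 ± 0.07 (adjusted p = 2.7e-14). The antiproliferative gene Btg2 rose by 2.88 ± 0.10 and the AP-1 subunit Junb by 2.49 ± 0.10. Arc, which acts at synapses in plasticity, rose by 2.34 ± 0.16, and Tiparp, a gene of the poly-ADP-ribose polymerase family, by 2.25 ± 0.06. Nr4a1 rose by 2.24 ± 0.18, Fos by 2.11 ± 0.12, and the MAP kinase phosphatase Dusp1 by 2.08 ± 0.07. Egr4 and Rgs1 followed at 2.04 ± 0.19 and 1.99 ± 0.11. The largest fall was that of Txnip, a thioredoxin-binding protein that limits glucose uptake (−0.89 ± 0.09, adjusted p = 1.1e-05).

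The D1 receptor's own gene, Drd1 (chromosome 17, 11101306 to 11103541), also rose after 60 min of SKF, by 0.53 ± 0.07 (adjusted p = 3.7e-05). Drd2 had a log2 fold change of 0.07 (adjusted p = 0.64). Egr1 rose by 1.48 ± 0.17, Npas4 by 1.81 ± 0.15, Fosb by 1.97 ± 0.18 and the neurotrophin gene Bdnf by 0.60 ± 0.12 (adjusted p = 0.0065). Of the 32 immediate early genes tested, 27 rose and 5 did not pass (27 up and 1 down adjusted over the list alone). Their median log2 change was 1.52 (camera adjusted p = 1.8e-67; adjusted p = 0.0049 with an estimated correlation). Of 34 later activity and cAMP response genes, 24 rose (26 up and 1 down adjusted over the list alone), with a median of 0.48 (camera adjusted p = 5.9e-43; adjusted p = 0.0046 with an estimated correlation). Among them the CREB target kinase Sik1 rose by 1.57 ± 0.04, the cAMP-responsive factor Crem by 1.58 ± 0.06 and Fbxo33 by 0.91 ± 0.05.

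Other gene groups moved less with SKF at 60 min. Of 33 striatal projection neuron genes 4 rose, over all genes and adjusted over the list alone. They were Drd1, Tac1, which encodes the substance P precursor of D1 neurons (0.66 ± 0.11), and the transcription factor genes Sp9 (0.23 ± 0.04) and Bcl11b (0.18 ± 0.04). The list median was 0.03, or −0.01 on FPKM as deposited (camera adjusted p = 0.022; adjusted p = 0.98 with an estimated correlation), and the list call ended without SKF replicate 6 of experiment 1 (median −0.009). Of 34 histone genes 3 fell (8 adjusted over the list alone), led by Hist2h4a at −0.20 ± 0.03, with a list median of −0.08 (camera adjusted p = 0.00012; adjusted p = 0.081 with an estimated correlation), or −0.11 in experiment 2 alone (camera adjusted p = 1.3e-05; adjusted p = 0.048 with an estimated correlation). Single genes of other lists that rose were Mepce, a capping enzyme of the 7SK RNA (0.36 ± 0.06), Fosl1 (1.83 ± 0.13), Nfkbia, which encodes an inhibitor of NF-kB (0.48 ± 0.05), and the sterol synthesis genes Cyp51 (0.36 ± 0.06) and Idi1 (0.49 ± 0.09).

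In all, 557 of 13999 genes tested passed an adjusted p of 0.05 with SKF at 60 min, 436 higher and 121 lower. At least a 2-fold rise was seen for 46 of them. On FPKM as deposited the split was 345 higher and 194 lower (64.0% higher against 78.3%). Experiment 1 alone gave 221 rises and 19 falls, and experiment 2 gave 283 rises and 42 falls. The experiments share no library, and 190 rises were common to both where 4.47 were expected for independent lists. All 221 genes that rose in experiment 1 had a log2 change above 0 in experiment 2. Nr4a2 rose by 2.66 ± 0.10 in experiment 1 and by 3.30 ± 0.10 in experiment 2, and Drd1 by 0.48 ± 0.09 and 0.58 ± 0.09. The call of Drd1 in experiment 1 ended without DMSO replicate 6 (0.45, adjusted p = 0.08) or SKF replicate 6 (0.34, adjusted p = 0.21). Without SKF replicate 6 the count of experiment 1 was 158, and without SKF replicate 2 that of experiment 2 was 204.

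**Figure D1:**
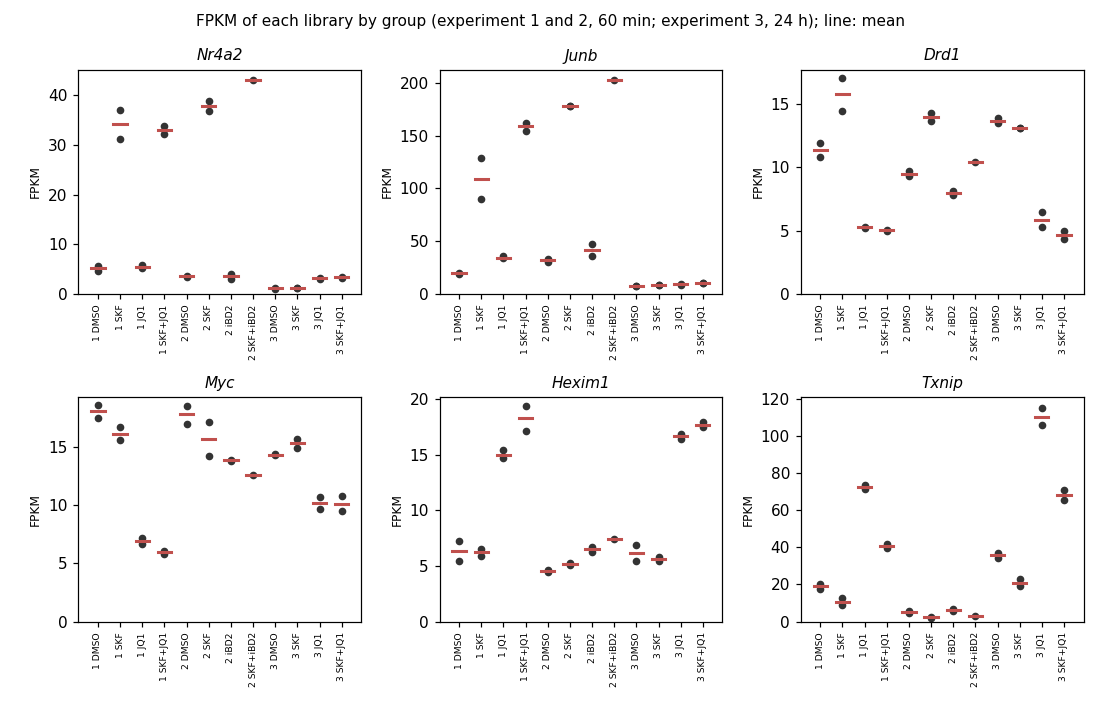
FPKM of Nr4a2, Junb, Drd1, Myc, Hexim1 and Txnip in each library, by experiment and group (horizontal axis), where each point is a library and each line a group mean. Nr4a2 stands at 34.2 and 37.8 FPKM in the SKF groups at 60 min and at 5.1 and 3.49 in DMSO, while Drd1 and Myc are lower in the JQ1 group (5.28 and 6.94) than in its DMSO group (11.4 and 18.1).

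The next comparison was JQ1 against DMSO at 60 min, without SKF. JQ1 raised Sertad1, a cell cycle regulator, from 1.52 ± 0.301 to 8.14 ± 0.29 FPKM (log2 fold change 2.13 ± 0.15, adjusted p = 6.7e-08). Txnip rose from 19.0 ± 1.98 to 72.3 ± 1.69 FPKM (1.94 ± 0.13, adjusted p = 1.2e-07). Hexim1, an inhibitor of the elongation kinase P-TEFb, rose by 1.23 ± 0.09 (adjusted p = 8.5e-08). Myc, the growth-promoting transcription factor gene, fell most, from 18.1 ± 0.753 to 6.94 ± 0.357 FPKM (−1.29 ± 0.08, adjusted p = 1.8e-08). The neuropeptide Y receptor gene Npy1r had −1.06 ± 0.09, and Drd1 fell from 11.4 ± 0.787 to 5.28 ± 0.0558 FPKM (−1.01 ± 0.09, adjusted p = 1.8e-06). The RNA-binding protein gene Rbm24 (−1.01 ± 0.11), the orphan receptor gene Gpr52 (−1.01 ± 0.09) and the activin subunit gene Inhba (−0.95 ± 0.13) fell too. The small nuclear RNA 7SK (−1.06 ± 0.23, adjusted p = 0.01) lost its call without DMSO replicate 6 (−0.97, adjusted p = 0.11), JQ1 replicate 5 (−1.01, adjusted p = 0.11) or JQ1 replicate 6 (−1.11, adjusted p = 0.057).

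Other large rises with JQ1 were those of LOC684762 (1.85 ± 0.09), H4f3 (1.74 ± 0.11), LOC684773 (1.62 ± 0.22) and the histone genes H2bc12 (1.61 ± 0.15) and Hist1h2bq (1.18 ± 0.04). Histone genes are near-identical copies of each other, and the values of single copies are uncertain because reads shared between them can be split. Of 34 histone genes 27 rose (30 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 8.1e-61; adjusted p = 8.9e-06 with an estimated correlation). Of 32 immediate early genes, 7 rose and 3 fell (11 and 4 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 4.7e-06; adjusted p = 0.82 with an estimated correlation). Jun rose by 0.92 ± 0.05, Jund by 0.51 ± 0.05, Ier2 by 1.12 ± 0.12 and Gadd45b by 1.25 ± 0.14. Fos had a log2 change of 0.58 (adjusted p = 0.09), Npas4 of 0.64 (adjusted p = 0.12), Nr4a1 of 0.32 (adjusted p = 0.65) and Arc of 0.22 (adjusted p = 0.76). Without either SKF library of experiment 1, Fos (adjusted p = 0.012) and Npas4 (adjusted p = 0.015) passed at the same fold changes.

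Among stress genes, 6 of 19 rose with JQ1 at 60 min (6 up and 1 down adjusted over the list alone), including the amino acid sensor gene Sesn2 (0.64 ± 0.07) and the heat shock gene Hspa1b (0.64 ± 0.11). Their median was 0.10 (camera adjusted p = 0.00038; adjusted p = 0.27 with an estimated correlation). Of 19 inflammatory and NF-kB genes 3 fell, likewise adjusted over the list alone, with a median of −0.14 (camera adjusted p = 0.012; adjusted p = 0.95 with an estimated correlation). Those that fell included the cyclooxygenase gene Ptgs2 (−1.0 ± 0.10) and Tnfaip3, whose product restrains NF-kB (−0.69 ± 0.12). Later activity genes went both ways, 5 up and 5 down (6 and 7 adjusted over the list alone), with Errfi1 at 0.89 ± 0.06 and Tiparp at 0.72 ± 0.09. The later activity list as a whole did not pass (camera adjusted p = 0.63). Of the BET and P-TEFb genes, 2 rose and 1 fell (camera adjusted p = 0.36). Microglia markers had a median of −0.03 (camera adjusted p = 0.42), and limma called 0 of the 16, with 1 lower at an unadjusted p under 0.05 and 0 by voom.

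At 60 min, 616 genes passed with JQ1, 261 higher and 355 lower (32.5% higher on FPKM as deposited against 42.4%), of which 37 rose and 7 fell at least 2-fold. The count was 359 without DMSO replicate 6, 316 without JQ1 replicate 5 and 391 without JQ1 replicate 6. The immediate early gene Egr1 (1.05 ± 0.24, adjusted p = 0.024) lost its call without any of the 4 DMSO and JQ1 libraries, with adjusted p of 0.11 and 0.098 without DMSO replicates 5 and 6 and 0.13 without either JQ1 library.

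JQ1 was next compared with vehicle in cultures that also received SKF. Drd1 fell most, from 15.8 ± 1.84 to 5.03 ± 0.0766 FPKM (−1.55 ± 0.09, adjusted p = 7.3e-09), and Myc had −1.37 ± 0.08. The poly(A) polymerase gene Tent5b (−1.14 ± 0.13), Tnfaip3 (−1.12 ± 0.12), the protease gene Adamts1 (−1.12 ± 0.11), the potassium channel gene Kcns2 (−1.11 ± 0.09), Ptgs2 (−1.08 ± 0.10) and the somatostatin receptor gene Sstr2 (−1.05 ± 0.10) followed. Txnip rose by 1.92 ± 0.13, Sertad1 by 1.84 ± 0.15 and Hexim1 by 1.48 ± 0.09. Of the genes SKF induces, Sik1 fell from 46.6 ± 1.76 to 30.9 ± 0.537 FPKM (−0.58 ± 0.05, adjusted p = 9.9e-07). Jun rose by 1.04 ± 0.05 and Ier5 by 1.17 ± 0.11. Arc had a log2 change of 0.55 (adjusted p = 0.21; 1.05, adjusted p = 0.00041, without SKF replicate 6) and Nr4a1 of 0.50 (adjusted p = 0.33).

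Fos passed as higher in SKF plus JQ1 than in SKF (0.72 ± 0.17, adjusted p = 0.022), and so did Npas4 (0.83 ± 0.21, adjusted p = 0.026), while Bdnf was lower (−0.66 ± 0.17, adjusted p = 0.026). The Fos call ended without SKF replicate 5 (0.41, adjusted p = 0.18), SKF plus JQ1 replicate 5 (0.75, adjusted p = 0.11) or replicate 6 (0.69, adjusted p = 0.12). For Npas4 the same omissions gave 0.46 (adjusted p = 0.19), 0.94 (adjusted p = 0.07) and 0.72 (adjusted p = 0.17). Bdnf had −0.42 (adjusted p = 0.31) without SKF replicate 6, −0.74 (adjusted p = 0.086) without SKF plus JQ1 replicate 5 and −0.59 (adjusted p = 0.18) without replicate 6.

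Histone genes rose again in the presence of SKF, 27 of 34 (31 adjusted over the list alone), with a median of 1.0 (camera adjusted p = 3.6e-47; adjusted p = 1.7e-05 with an estimated correlation). Of 91 ribosomal protein genes 8 rose (28 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 5.8e-15; adjusted p = 0.69 with an estimated correlation). Of 32 immediate early genes 10 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 6.6e-08; adjusted p = 0.69 with an estimated correlation). With 1 library left out that median ran from 0.179 to 0.716. Inflammatory genes fell in 4 of 19 (5 adjusted over the list alone), with a median of −0.10 (camera adjusted p = 0.014; adjusted p = 0.95 with an estimated correlation), a call that ended without SKF replicate 5 (median −0.005). Later activity genes were split between 6 rises and 11 falls (7 and 11 adjusted over the list alone; camera adjusted p = 0.17).

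With SKF present, 916 genes passed for JQ1, 383 higher and 533 lower. This set and the comparison without SKF share no library, and 210 rises (7.14 expected) and 256 falls (13.5 expected) were common to both. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.56 and a Spearman correlation of 0.46. The count was 610 without SKF replicate 6, 450 without SKF plus JQ1 replicate 5 and 576 without SKF plus JQ1 replicate 6.

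Whether JQ1 alters the response to SKF was tested directly as the difference between the SKF effects with and without JQ1. Sik1 was the single gene that passed: its SKF response was lower by a log2 difference of −0.49 ± 0.07 (adjusted p = 0.047), and limma voom gave −0.50 (adjusted p = 0.0098). Drd1 had a difference of −0.54 (95% confidence interval −0.82 to −0.26, adjusted p = 0.95). For Fos the difference was 0.14 (−0.39 to 0.67), for Arc 0.33 (−0.36 to 1.03), for Nr4a1 0.18 (−0.58 to 0.94) and for Npas4 0.19 (−0.44 to 0.81), and each turned to between −0.19 and −0.17 without SKF replicate 5. Across all genes 459 had an unadjusted p under 0.05. The Sik1 call ended with a pseudocount of 0.1 (adjusted p = 0.055), with the replicate number as a block (adjusted p = 0.067) and with experiment 1 fitted alone (adjusted p = 0.95). It also ended in 21 of 23 omissions of a library, 0 genes passed in 19 of them (0 to 3 over all), and 3 passed without SKF replicate 5.

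Of 21 lists 8 passed for the SKF by JQ1 difference at 60 min at the preset correlation, and 0 with an estimated one (adjusted p of 0.47 to 0.98). Cholesterol genes (median −0.20, camera adjusted p = 4.9e-05), mitochondrially encoded genes (−0.18, camera adjusted p = 0.0028), histone genes (−0.11, camera adjusted p = 0.028), striatal genes (−0.07, camera adjusted p = 0.044) and synapse genes (−0.07, camera adjusted p = 0.042) had negative differences. Ribosomal protein genes (0.08, camera adjusted p = 4.3e-08), astrocyte markers (0.14, camera adjusted p = 0.0039) and microglia markers (0.14, camera adjusted p = 0.029) had positive ones. Limma called none of their genes over all genes tested, nor did voom; adjusted over the list alone 1 striatal and 1 histone gene were lower. At an unadjusted p under 0.05 there were 4 lower and 1 higher histone genes, 2 lower cholesterol genes, 1 lower striatal gene, 3 higher ribosomal protein genes and 1 higher microglia marker. Without SKF replicate 6 the calls of cholesterol (0.044), synapse (0.02), striatal (−0.002) and histone genes (−0.087) and of astrocyte (−0.009) and microglia markers (−0.073) ended, and that of mitochondrially encoded genes ended without DMSO replicate 5 (0.019). Each other library of experiment 1 but SKF replicate 5 also ended at least 1 of these calls. The ribosomal protein call held in every omission, judged by an unadjusted camera p under 0.05.

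The genes induced by SKF were also followed as a set, chosen in 1 experiment and tested in the other. The group means of both steps thus came from different libraries. Each step still drew the spread, the filter and the scaling from all 23 libraries. The 283 genes that rose with SKF in experiment 2 had a median SKF response of 0.40 in experiment 1, where 280 lay above 0. With JQ1 added to SKF, 48 of the 283 were higher and 83 lower than with SKF alone, and the median was −0.07 (camera adjusted p = 0.0019; adjusted p = 0.45 with an estimated correlation). The median difference between SKF responses was −0.08 (camera adjusted p = 1.8e-10; adjusted p = 0.16 with an estimated correlation), and the mean response was 0.57 without and 0.49 with JQ1, 14.8% lower. The SKF libraries of experiment 1 set these values: for these 283 genes the median JQ1 effect was −0.01 and the median difference −0.03, no longer past the threshold, without SKF replicate 6, and they were −0.11 and −0.15 without SKF replicate 5.

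**Figure D2:**
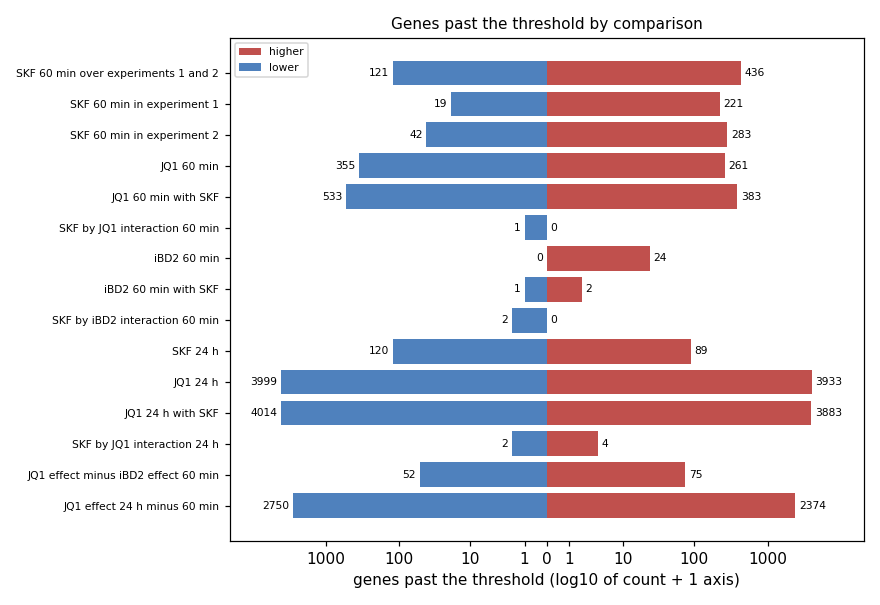
Numbers of genes past an adjusted p of 0.05 (horizontal axis, log10 of the count plus 1) for each comparison, higher to the right and lower to the left of 0. Counts run from 1 for the SKF by JQ1 difference at 60 min to 7932 for JQ1 at 24 h.

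The inhibitor iBD2 was compared with DMSO at 60 min in experiment 2. Histone genes were among those that rose. Of 2 genes that share the symbol Hist1h2ail1, 1 rose by 0.64 ± 0.07 (adjusted p = 0.0012), and this gene and Hist1h2bq (0.37 ± 0.04, adjusted p = 0.0012) kept their calls in every fit with a library left out. The larger rises of hist1h2ail2 (0.94 ± 0.14) and Hist1h3b (0.93 ± 0.13), both with an adjusted p of 0.0073, did not. They had adjusted p of 0.14 and 0.11 without iBD2 replicate 1, hist1h2ail2 had 0.10 without DMSO replicate 2, and Hist1h3b had 0.11 without DMSO replicate 1 and 0.072 without iBD2 replicate 2. LOC102548682 (0.71 ± 0.11, adjusted p = 0.012) had adjusted p of 0.086, 0.12 and 0.14 without DMSO replicate 2 and iBD2 replicates 1 and 2. Hexim1 rose by 0.52 ± 0.09 (adjusted p = 0.023), a call lost without DMSO replicate 1 (adjusted p = 0.14) or 2 (0.16) or iBD2 replicate 1 (0.11) or 2 (0.30). Myc (−0.30, adjusted p = 0.34), Drd1 (−0.20, adjusted p = 0.76) and Fos (0.35, adjusted p = 0.78) did not pass.

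As a list, 9 of 34 histone genes rose with iBD2 (21 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 1.1e-32; adjusted p = 5.8e-05 with an estimated correlation). Immediate early genes had a median of 0.24, or 0.13 to 0.343 with 1 library left out (camera adjusted p = 8.1e-09; adjusted p = 0.62 with an estimated correlation). None of them was called by limma, over all genes or adjusted over the list alone, against 8 higher at an unadjusted p under 0.05 and 0 called by voom. Of the 12 BET and P-TEFb genes 1 rose, Hexim1, likewise adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.013; adjusted p = 0.16 with an estimated correlation), and the list call ended without DMSO replicate 1 (median 0.059). Altogether 24 genes rose and 0 fell in the limma test, against 491 higher and 432 lower at an unadjusted p under 0.05, and limma voom called 3 and 1. The count of 24 was 10 and 9 without DMSO replicates 1 and 2, 5 without either iBD2 library, 15 without either JQ1 library of experiment 3, and 15 and 14 without SKF replicates 5 and 6 of experiment 3.

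In cultures with SKF, the lone SKF plus iBD2 library was set against SKF, on the assumption that it varied like the other groups. Hist1h2ail1 (0.67 ± 0.09, adjusted p = 0.0041) and Hist1h2bq (0.48 ± 0.06, adjusted p = 0.00078) rose again. Vps25, a subunit of the ESCRT-II sorting complex, had −3.34 ± 0.07 (adjusted p = 4.2e-15), a value that is uncertain because an overlapping gene took up the coverage in that library. Drd1 had −0.41 (adjusted p = 0.64) and Hexim1 0.48 (adjusted p = 0.30). Of 34 histone genes 2 rose (17 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 5.6e-23; adjusted p = 0.00027 with an estimated correlation). No other gene passed at 13999 genes tested, 696 had an unadjusted p under 0.05, and limma voom called 5. The count of 3 was 6 without either DMSO library of experiment 1, and 5 without either DMSO library of experiment 2 or 3 or without SKF replicate 1 of experiment 2.

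For the SKF response with and without iBD2, 2 genes passed, Vps25 (−3.34 ± 0.09, adjusted p = 2.9e-13) and the splicing factor gene Sf3b6 (−0.85 ± 0.12, adjusted p = 0.022). The Vps25 value rests on the lone SKF plus iBD2 library, where the overlapping gene took up the coverage, so it does not show a changed response. Voom gave Sf3b6 −0.92 with an adjusted p of 1, and its limma call ended without DMSO replicate 2 (adjusted p = 0.076), SKF replicate 1 (0.13) or 2 (0.057) or iBD2 replicate 1 (0.18) or 2 (0.075). The count was 4 without DMSO replicate 2 and 1 without either SKF or either iBD2 library. For Fos the difference was −0.14 (95% confidence interval −0.73 to 0.46; 0.02 without iBD2 replicate 1) and for Drd1 −0.21 (−0.53 to 0.10). Of the 221 genes that rose with SKF in experiment 1, all lay above 0 with SKF in experiment 2, with a median of 0.57. Adding iBD2 to SKF gave them a median of −0.02 (camera adjusted p = 0.033; adjusted p = 0.57 with an estimated correlation). Limma called 0 of them, with 5 higher and 14 lower at an unadjusted p under 0.05 and 0 by voom. The median difference of SKF responses was −0.03 (camera adjusted p = 0.0048; adjusted p = 0.45 with an estimated correlation), and the mean response was 0.75 without and 0.70 with iBD2. The call of the iBD2 effect on the set, chosen anew in each fit, ended without DMSO replicate 5 (median −0.017) or SKF replicate 6 (−0.008) of experiment 1 or SKF replicate 1 of experiment 2 (−0.011).

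Both inhibitors were then compared at the shared time of 60 min by testing the difference of their effects. The labels give no doses, and each inhibitor was used in its own experiment, so inhibitor and experiment cannot be told apart here. JQ1 had the larger effect on Txnip (difference 1.64 ± 0.19, adjusted p = 0.00025), H2ac20 (1.53 ± 0.18), H4f3 (1.45 ± 0.16) and Sertad1 (1.38 ± 0.21, adjusted p = 0.0024). Myc (−0.99 ± 0.12, adjusted p = 0.00016), RGD1309028 (−0.95 ± 0.15), Fam181a (−0.93 ± 0.13), Npy1r (−0.92 ± 0.13) and Drd1 (−0.81 ± 0.13, adjusted p = 0.0042) were lower under JQ1 than under iBD2, each relative to its own DMSO. Jun differed by 0.80 ± 0.07 and Sesn2 by 0.59 ± 0.10. Hexim1 differed by 0.71 ± 0.13 (adjusted p = 0.0078; 0.68 and 0.053 without JQ1 replicate 5).

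Among 34 histone genes 14 rose more with JQ1 (26 adjusted over the list alone), with a median difference of 0.63 (camera adjusted p = 5.5e-38; adjusted p = 3.5e-05 with an estimated correlation). In all 127 genes differed, 75 higher and 52 lower with JQ1. Of the 24 genes that rose with iBD2, 20 also rose with JQ1, where 0.447 were expected for independent lists. Of the 261 genes that rose with JQ1, 208 lay above 0 with iBD2, and of the 355 that fell 273 lay below 0. Across genes, which are not independent replicates, Pearson's correlation of the effects was 0.24 and Spearman's 0.17. The count of 127 was 76 without DMSO replicate 6, 66 without JQ1 replicate 5 and 65 without JQ1 replicate 6 of experiment 1, and 82 without DMSO replicate 1 of experiment 2.

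**Figure D3:**
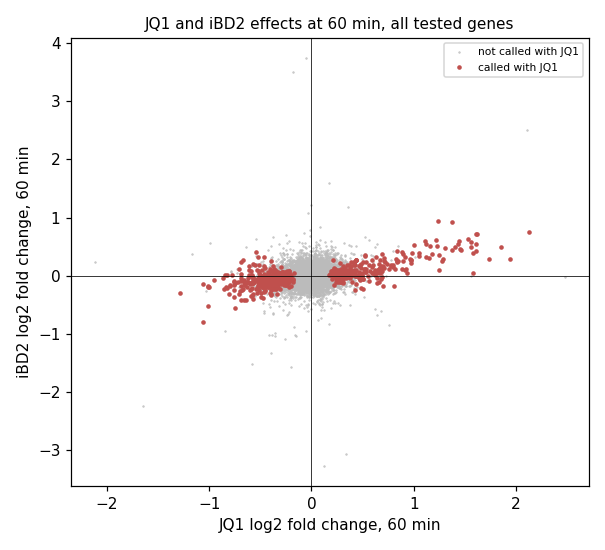
Log2 fold change of each tested gene at 60 min with JQ1 (horizontal axis) and with iBD2 (vertical axis), with the 616 genes that passed for JQ1 in red. The genes that rose with JQ1 have a median of 0.44 with JQ1 and 0.09 with iBD2, and those that fell −0.40 and −0.08.

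SKF was then compared with DMSO after 24 h. Vegfa, the vascular growth factor gene, went from 5.94 ± 0.244 to 15.4 ± 0.699 FPKM (1.31 ± 0.08, adjusted p = 8e-08). The transferrin receptor gene Tfrc rose by 1.26 ± 0.09 and the secreted neuropeptide precursor gene Vgf by 1.23 ± 0.13. AABR07051069.1 (1.21 ± 0.12), Ankrd37 (1.15 ± 0.17), the adenylate kinase gene Ak4 (1.07 ± 0.16), the nuclear receptor gene Nr4a3 (0.65 ± 0.10) and the lactate dehydrogenase gene Ldha (0.64 ± 0.06) rose as well. The amino acid transporter gene Slc7a3 (0.68 ± 0.11, adjusted p = 0.003) had adjusted p of 0.07 without DMSO replicate 5 and 0.11 without SKF replicate 6. The falls were led by genes of microglia and other myeloid cells: the Fc receptor gene Fcgr3a (−1.83 ± 0.13, adjusted p = 6.7e-07), the fractalkine receptor gene Cx3cr1 (−1.55 ± 0.14), Evi2b (−1.30 ± 0.18), the phospholipase family gene Pld4 (−1.19 ± 0.12) and Clec4a1 (−1.18 ± 0.14). The microglia marker Aif1 (−1.20 ± 0.24, adjusted p = 0.015) had −0.99 (adjusted p = 0.22) and −0.84 (adjusted p = 0.32) without DMSO replicate 5 and SKF replicate 6. Fos had a log2 change of 0.25 (adjusted p = 0.75) and Drd1 of −0.05 (adjusted p = 0.93).

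Of the 16 microglia markers 11 fell at 24 h of SKF and 5 did not pass (16 fell adjusted over the list alone). Their median was −0.96 (camera adjusted p = 7.8e-29; adjusted p = 0.035 with an estimated correlation). The lysosomal marker Cd68 had −0.99 ± 0.15. Tyrobp (−0.97, adjusted p = 0.0017) had an adjusted p of 0.056 without SKF replicate 6, and Trem2 (−1.03, adjusted p = 0.0018) had 0.071 without it and 0.059 without DMSO replicate 5. Stress genes rose in 7 of 19, likewise adjusted over the list alone, with a median of 0.18 (camera adjusted p = 7.9e-08; adjusted p = 0.048 with an estimated correlation). With 1 library left out that median ran from 0.094 to 0.251. Among the stress genes that rose were the asparagine synthetase gene Asns (0.50 ± 0.05) and its regulator Atf4 (0.37 ± 0.05). Inflammatory genes had a median of −0.10 with 1 fall, the complement gene C3 (2 falls adjusted over the list alone; camera adjusted p = 0.0087; adjusted p = 0.95 with an estimated correlation). C3 itself (−0.74, adjusted p = 0.0079) had adjusted p of 0.15 and 0.16 without DMSO replicate 5 and SKF replicate 6.

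Astrocyte markers had a median of −0.18 with SKF at 24 h (camera adjusted p = 0.0047; adjusted p = 0.98 with an estimated correlation) and cholesterol synthesis genes a median of 0.16 (camera adjusted p = 6e-05; adjusted p = 0.95 with an estimated correlation). Both list calls ended without DMSO replicate 5 (medians −0.023 and 0.045). Limma called 0 genes of either list, also adjusted over the list alone, with 1 lower astrocyte marker and 4 higher cholesterol genes at an unadjusted p under 0.05 and 0 by voom. In all 209 genes passed, 89 higher and 120 lower, with 80 without DMSO replicate 5 and 62 without SKF replicate 6. Of the 436 genes that rose at 60 min, 8 also rose at 24 h (2.77 expected) and 4 fell. The times come from different experiments, so time and experiment cannot be told apart.

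**Figure D4:**
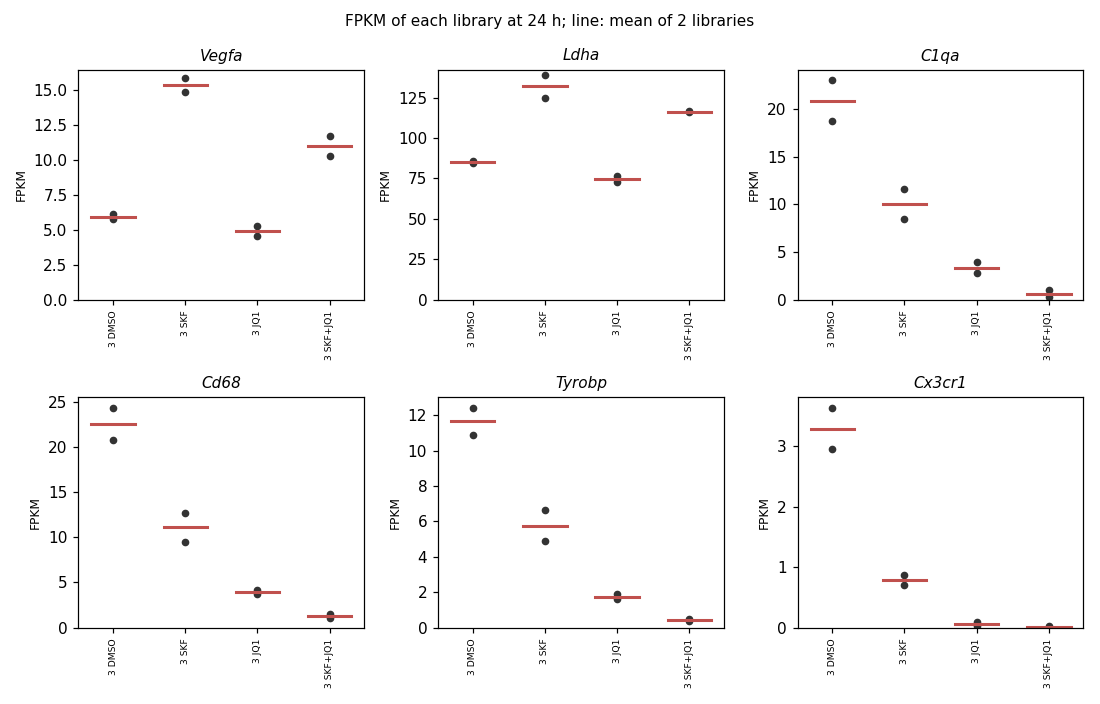
FPKM of Vegfa, Ldha, C1qa, Cd68, Tyrobp and Cx3cr1 in each library of the 24 h experiment, by group (horizontal axis), where each point is a library and each line a mean. Cd68 has means of 22.5 FPKM in DMSO, 11.1 in SKF, 3.9 in JQ1 and 1.31 in SKF plus JQ1, and Vegfa 5.94 in DMSO and 15.4 in SKF.

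JQ1 for 24 h moved more genes than any other treatment: 7932 of 13999 passed, 3933 higher and 3999 lower, with 86 rises and 498 falls of at least 2-fold. Fcer1g, the Fc receptor gamma chain gene of myeloid cells, fell from 26.2 ± 1.42 to 2.90 ± 0.287 FPKM (−2.89 ± 0.12, adjusted p = 5e-11), and Fcrl2 had −3.30 ± 0.20, Tmem270 −2.85 ± 0.20, the chemokine gene Ccl6 −2.76 ± 0.21, the interferon-induced gene Ifitm3 −2.76 ± 0.24, Clec4a1 −2.74 ± 0.14 and Cx3cr1 −2.72 ± 0.14. Akap13, a scaffold that binds protein kinase A, rose from 1.08 ± 0.075 to 4.95 ± 0.0674 FPKM (1.87 ± 0.08, adjusted p = 3.1e-11). LOC102548682 (2.30 ± 0.11), LOC100912564 (1.90 ± 0.11) and AABR07012583.2 (1.83 ± 0.07) rose too. Txnip rose by 1.72 ± 0.13, Sertad1 by 1.60 ± 0.15, H4f3 by 1.60 ± 0.11, Hist1h2bq by 1.70 ± 0.04, the DNA-damage histone gene H2ax by 1.60 ± 0.05 and the transcobalamin receptor gene Cd320 by 1.57 ± 0.09. Hexim1 rose by 1.47 ± 0.09, and Myc fell (−0.38 ± 0.08). Drd1 fell from 13.7 ± 0.289 to 5.86 ± 0.837 FPKM (−1.07 ± 0.09). On FPKM as deposited the split was 2588 higher and 4963 lower (34.3% higher against 49.6%), and the median of all genes was −0.08 in place of 0.01.

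Neuronal lists moved in both directions with JQ1 at 24 h, and none of those named here passed as a list. Of 33 striatal genes 7 rose and 11 fell, the same counts as adjusted over the list alone (median −0.05, camera adjusted p = 0.38). Ptpn5, the striatum-enriched tyrosine phosphatase gene, fell (−1.37 ± 0.08), as did the prodynorphin gene Pdyn (−0.97 ± 0.08) and the retinoid receptor gene Rxrg (−0.74 ± 0.07). Drd2 had −0.12 (adjusted p = 0.19), −0.22 (adjusted p = 0.013) on FPKM as deposited and −0.23 (adjusted p = 0.032) without DMSO replicate 5. Of 35 synapse genes 8 rose and 13 fell, likewise adjusted over the list alone (median −0.03, camera adjusted p = 0.36), with the AMPA receptor genes Gria1 at −0.80 ± 0.04 and Gria3 at −0.99 ± 0.08. Of 33 ion channel genes 3 rose and 12 fell, likewise over the list alone (median −0.05, camera adjusted p = 0.14), among them the sodium channel gene Scn3a (−0.55 ± 0.04) and the potassium channel gene Kcnc2 (−0.82 ± 0.08). Of 17 excitatory neuron and interneuron markers 4 rose and 6 fell, likewise over the list alone (median −0.06, camera adjusted p = 0.42), with Calb2, the calretinin gene, at −1.57 ± 0.10. On FPKM as deposited, where the median of all genes was −0.08, the medians were −0.14 for striatal, −0.13 for synapse and −0.15 for ion channel genes and −0.16 for excitatory neuron and interneuron markers.

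Activity genes were partly higher after 24 h of JQ1. Of 32 immediate early genes 17 rose and 3 fell, likewise adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.011; adjusted p = 0.98 with an estimated correlation). Jun rose by 1.02 ± 0.05, Nr4a3 by 1.45 ± 0.10, Nr4a2 by 1.29 ± 0.10, Fos by 1.17 ± 0.17 and Npas4 by 1.0 ± 0.21. Arc had −0.18 (adjusted p = 0.52). Bdnf rose by 0.85 ± 0.17. Later activity genes had 12 rises and 10 falls, likewise over the list alone (median 0.03, or −0.06 on FPKM as deposited; camera adjusted p = 0.70).

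Microglia markers fell in 15 of 16 with JQ1 at 24 h, likewise adjusted over the list alone, with a median of −1.94 (camera adjusted p = 2.7e-09; adjusted p = 0.38 with an estimated correlation), and Tyrobp had −2.37 ± 0.15, Trem2 −2.46 ± 0.16 and Cd68 −2.30 ± 0.15. Beside that fall, inflammatory genes fell in 13 of 19 (likewise over the list alone; median −0.55, camera adjusted p = 0.0023; adjusted p = 0.82 with an estimated correlation), including the chemokine genes Ccl2 (−1.71 ± 0.19) and Ccl7 (−1.60 ± 0.19). Interferon response genes fell in 6 of 10 (likewise over the list alone; median −0.56, camera adjusted p = 0.035; adjusted p = 0.86 with an estimated correlation), led by Mx2 at −1.74 ± 0.10. Astrocyte markers had 1 rise and 7 falls (likewise over the list alone; median −0.24, camera adjusted p = 0.17), with the water channel gene Aqp4 at −1.95 ± 0.18. Oligodendrocyte markers had 3 rises and 5 falls (likewise; median −0.01, or −0.10 on FPKM as deposited; camera adjusted p = 0.67), and matrix and fibroblast genes 3 rises and 8 falls (likewise; median −0.29, camera adjusted p = 0.31). Of the endothelial and mural markers, 2 were tested, too few for a list test, and Cspg4 fell (−0.45 ± 0.10).

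Among housekeeping groups, 66 of 91 ribosomal protein genes rose with JQ1 at 24 h (69 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 2e-11; adjusted p = 0.82 with an estimated correlation). Of 91 respiratory chain genes 14 rose and 30 fell (14 and 29 over the list alone; median −0.05, camera adjusted p = 0.37), and of 13 mitochondrially encoded genes 11 rose (likewise over the list alone; median 0.31, camera adjusted p = 0.054). Histone genes had 23 rises and 5 falls (25 and 5 over the list alone; median 0.84, camera adjusted p = 3e-06; adjusted p = 0.035 with an estimated correlation). Of 24 cell cycle genes 13 rose and 2 fell, likewise over the list alone (median 0.27, camera adjusted p = 0.014; adjusted p = 0.38 with an estimated correlation), among them the mitotic kinase gene Aurkb (1.31 ± 0.13) and the proliferation marker Mki67 (0.71 ± 0.10). Of 12 BET and P-TEFb genes 9 rose and 1 fell, likewise over the list alone (median 0.26, camera adjusted p = 0.016; adjusted p = 0.18 with an estimated correlation), with the kinase gene Cdk9 at 0.47 ± 0.06. Stress genes (11 up, 5 down; 11 and 6 over the list alone; median 0.15, mean −0.00; camera adjusted p = 0.29), cholesterol genes (3 up, 5 down, likewise over the list alone; median −0.00; camera adjusted p = 0.81) and the 11 genes reported by others to respond to BET inhibitors (5 up, 5 down, likewise over the list alone; median 0.12; camera adjusted p = 0.75) did not pass as lists. On FPKM as deposited the medians were 0.16 for BET and P-TEFb, 0.06 for stress, −0.09 for cholesterol and −0.14 for respiratory chain genes and 0.03 for the reported responders, against −0.08 for all genes.

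**Figure D5:**
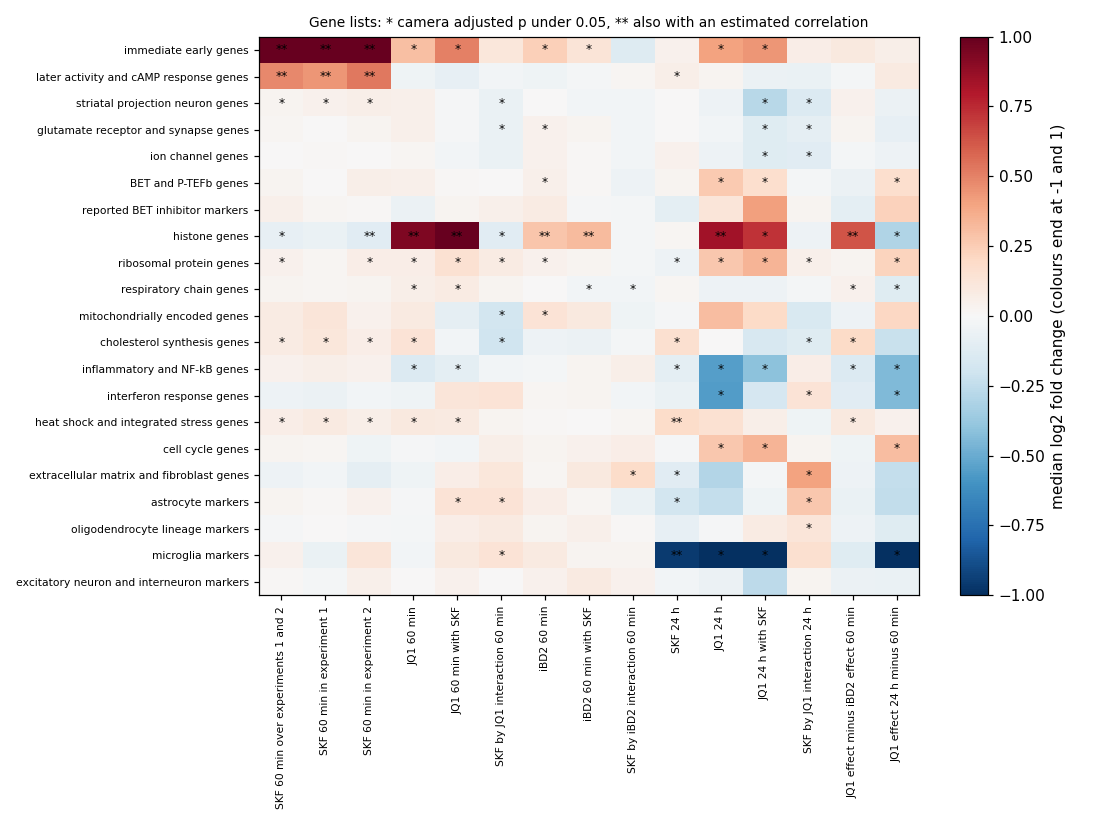
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis); colours end at −1 and 1, one star marks a camera adjusted p under 0.05 and a double star one that also holds with an estimated correlation. Histone genes have medians of 0.93 with JQ1 and 0.28 with iBD2 at 60 min, and microglia markers of −0.96 with SKF and −1.94 with JQ1 at 24 h.

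With SKF present throughout the 24 h, 7897 genes passed for JQ1, 3883 higher and 4014 lower (38.1% higher on FPKM as deposited against 49.2%). Of the rises, 3277 were shared with the comparison without SKF (1090 expected), and of the falls 3392 (1150 expected), between sets with no library in common. The complement genes C1qc (−3.75 ± 0.18), C1qb (−3.20 ± 0.19) and C1qa (−3.20 ± 0.25), Fcer1g (−3.73 ± 0.12) and Fcrl2 (−3.39 ± 0.20) fell most, and LOC102548682 (2.20 ± 0.11), Akap13 (2.12 ± 0.08) and LOC100912564 (2.0 ± 0.11) rose most. Drd1 (−1.34 ± 0.09), Ptpn5 (−1.61 ± 0.08) and the adenosine receptor gene Adora2a, a marker of D2 neurons (−1.44 ± 0.11), fell. Drd2 fell (−0.28 ± 0.08), a call lost without SKF plus JQ1 replicate 5 (−0.16, adjusted p = 0.11). Ion channel genes fell in 16 of 33 and 1 rose, likewise adjusted over the list alone (median −0.12, camera adjusted p = 0.0056; adjusted p = 0.98 with an estimated correlation). Synapse genes had 4 rises and 16 falls, likewise over the list alone (median −0.12, camera adjusted p = 0.035; adjusted p = 0.98 with an estimated correlation), and striatal genes 8 rises and 15 falls (8 and 16 over the list alone; median −0.28, camera adjusted p = 0.048; adjusted p = 0.98 with an estimated correlation). Both of these list calls ended without SKF plus JQ1 replicate 5 (medians −0.027 and −0.058). On FPKM as deposited the ion channel and synapse medians were −0.19.

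Some lists had more calls with SKF present than without it and others fewer. Ribosomal protein genes rose in 74 of 91 (76 adjusted over the list alone; median 0.34, camera adjusted p = 1.5e-14; adjusted p = 0.70 with an estimated correlation), and cell cycle genes had 14 rises and 2 falls (15 and 2 over the list alone; median 0.34, camera adjusted p = 0.008; adjusted p = 0.32 with an estimated correlation). Microglia markers had 1 rise and 15 falls (likewise over the list alone; median −1.44, camera adjusted p = 1.4e-07; adjusted p = 0.53 with an estimated correlation), and histone genes 21 rises and 5 falls (likewise; median 0.72, camera adjusted p = 5.5e-05; adjusted p = 0.065 with an estimated correlation). Several microglia markers lay under the pseudocount of 0.5 FPKM in SKF plus JQ1 (Cx3cr1 0.017, Trem2 0.02). The log2 scale leaves them little room to fall, so the microglia median does not show a weaker JQ1 effect with SKF. Immediate early genes had 15 rises and 2 falls (likewise; median 0.44, camera adjusted p = 0.0039; adjusted p = 0.98 with an estimated correlation), and BET and P-TEFb genes 7 rises and 1 fall (likewise; median 0.17, or 0.10 on FPKM as deposited; camera adjusted p = 0.029; adjusted p = 0.25 with an estimated correlation). Inflammatory genes fell in 10 of 19 (likewise; median −0.41, camera adjusted p = 0.007; adjusted p = 0.95 with an estimated correlation). Of 13 mitochondrially encoded genes limma called 0, also adjusted over the list alone, with 3 higher at an unadjusted p under 0.05 and 2 higher by voom (median 0.19, camera adjusted p = 0.29). Interferon response genes fell in 3 of 10, likewise over the list alone (median −0.17, camera adjusted p = 0.20), and astrocyte markers had 5 rises and 4 falls, likewise (median −0.04, camera adjusted p = 0.91). Cholesterol genes had 2 rises and 8 falls, likewise (median −0.16, camera adjusted p = 0.23), and the 11 reported BET inhibitor markers 6 rises and 5 falls, likewise (median 0.41, camera adjusted p = 0.57).

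The SKF response at 24 h differed with JQ1 in 6 genes. Fcgr3a (1.78 ± 0.19, adjusted p = 0.00056), Cx3cr1 (1.42 ± 0.20, adjusted p = 0.0091) and Clec4a1 (1.16 ± 0.20, adjusted p = 0.049) had positive differences. These genes and Ltc4s (1.37 ± 0.23, adjusted p = 0.049) lay under the pseudocount of 0.5 FPKM in both JQ1 groups, where the log2 scale leaves little room for a further fall, so their differences do not show a smaller response to SKF. Cx3cr1 had 3.29 FPKM in DMSO, 0.789 in SKF, 0.0621 in JQ1 and 0.017 in SKF plus JQ1, and Ltc4s was listed at 0 in both JQ1 groups. Igf1, the insulin-like growth factor gene, had the opposite sign (−0.76 ± 0.11, adjusted p = 0.012). The remaining gene was AABR07017159.1 (−1.27 ± 0.16). The call of Clec4a1 ended in 20 omissions of a library, that of Ltc4s in 17 and that of Igf1 in 6, with adjusted p of 0.053 to 0.11 for Igf1 without either DMSO library, JQ1 replicate 6, SKF replicate 5 or either SKF plus JQ1 library. The count was 3 without either DMSO library, JQ1 replicate 6, SKF replicate 5 or either SKF plus JQ1 library, and without DMSO replicate 5, SKF replicate 6 or SKF plus JQ1 replicate 6 Cx3cr1 had adjusted p of 0.053, 0.07 and 0.052. Voom called neither Fcgr3a (3.53, adjusted p = 0.43), Cx3cr1 (−0.20, adjusted p = 1), Ltc4s (4.07, adjusted p = 0.53) nor Clec4a1 (0.96, adjusted p = 0.97), and called Igf1 (−0.83, adjusted p = 0.041) and AABR07017159.1 (−5.44, adjusted p = 0.041). With experiment 3 fitted alone Fcgr3a passed (adjusted p = 0.04) and the others had adjusted p of 0.11 to 0.61. A pseudocount of 0.1 ended the calls of Cx3cr1 (adjusted p = 0.16) and Clec4a1 (0.37), a pseudocount of 1 that of Ltc4s (0.092), and the replicate block (0.14 and 0.10) and the fit without a filter (0.069 and 0.064) those of Clec4a1 and Ltc4s.

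As lists, 9 of 21 passed for this difference at the preset correlation and 0 with an estimated one (adjusted p of 0.70 to 0.98). Astrocyte markers (median 0.27, camera adjusted p = 3.6e-07), matrix and fibroblast genes (0.40, camera adjusted p = 3e-04), interferon response genes (0.14, camera adjusted p = 0.035), oligodendrocyte markers (0.12, camera adjusted p = 0.0094) and ribosomal protein genes (0.05, or 0.08 on FPKM as deposited; camera adjusted p = 0.0011) had positive differences. Striatal genes (−0.14, camera adjusted p = 0.00041), synapse genes (−0.09, camera adjusted p = 0.00053), ion channel genes (−0.11, camera adjusted p = 0.0023) and cholesterol genes (−0.12, camera adjusted p = 0.0052) had negative ones. Mitochondrially encoded genes (−0.15, camera adjusted p = 0.069) and histone genes (−0.05, camera adjusted p = 0.14) did not pass. In each of these lists limma called 0 genes, also adjusted over the list alone, and so did voom. At an unadjusted p under 0.05 the striatal list had 2 higher and 5 lower, the histone list 2 and 6, the ion channel list 3 lower, the astrocyte, matrix and interferon lists 2 higher each and the oligodendrocyte list 1. Judged by an unadjusted camera p under 0.05, the astrocyte call held in every omission of a library, with medians of 0.128 to 0.422. Without SKF plus JQ1 replicate 5 the calls of matrix (0.14), oligodendrocyte (0.044), ribosomal (0.013), striatal (−0.036), synapse (−0.006), ion channel (0.005) and cholesterol genes (−0.067) ended, without DMSO replicate 5 those of interferon (0.084), ribosomal (−0.014), striatal (−0.061), synapse (−0.027), ion channel (−0.04) and cholesterol genes (−0.054). Without JQ1 replicate 6 those of oligodendrocyte (0.05), striatal (−0.066), synapse (−0.062), ion channel (−0.029) and cholesterol genes (−0.081) ended, and that of interferon genes without SKF replicate 6 (0.087) or without a filter (0.096).

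Last, the JQ1 effects at 24 h and 60 min were compared, again across experiments. Akap13 (difference 2.06 ± 0.12), Nr4a3 (1.85 ± 0.15) and Cd320 (1.49 ± 0.12) rose more at 24 h, and Fcrl2 (−3.36 ± 0.28) and Fcer1g (−2.86 ± 0.17) fell more. The effect on Myc was smaller at 24 h (difference 0.91 ± 0.12, adjusted p = 1.5e-05), and Bdnf differed by 1.17 ± 0.25. Hexim1 (0.24, adjusted p = 0.15) and Drd1 (−0.06, adjusted p = 0.75) did not differ past the threshold. Microglia markers were lower in 14 of 16, likewise adjusted over the list alone (median −1.86, camera adjusted p = 1.4e-10; adjusted p = 0.32 with an estimated correlation), and histone genes had 4 rises and 13 falls, likewise (median −0.30, camera adjusted p = 0.031; adjusted p = 0.49 with an estimated correlation). In all 5124 genes differed, 2374 higher and 2750 lower at 24 h (31.8% higher on FPKM as deposited against 46.3%). Of the 261 genes that rose with JQ1 at 60 min 224 also rose at 24 h (73.3 expected), and of the 355 that fell 196 also fell, while 6 and 25 went the opposite way.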

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

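All tests of explanations in this part were chosen after the result was seen, except the comparison of the SKF-induced set with random lists matched on expression. Results stand here because a test of a difference between effects passed, except the count for SKF at 60 min and the microglia markers with SKF at 24 h, which are added for a closer look. The count for SKF at 60 min was also set against other splits of its 8 libraries into groups of 4, with the experiment as a term. The real split called 412 genes, 1 of 34 splits reached that number, the real one itself, and the highest of the others was 1 gene. Each of the other splits put SKF and DMSO libraries in the same group, and the libraries may be technical replicates, so chance is not excluded.

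Microglia markers fell with SKF at 24 h. In the separate JQ1 libraries, SKF plus JQ1 against JQ1, 7 of the 16 fell (median of all 16 −0.43, Cd68 −1.33 ± 0.15, Tyrobp −1.32 ± 0.15), which argues against a chance difference in the DMSO and SKF libraries alone. Over 7 markers with at least 4 FPKM in DMSO the log2 ratios ran from −1.11 to −0.96, with an SD of 0.048 (Cd68 22.5 to 11.1 FPKM, Tyrobp 11.7 to 5.75), but 1 marker had been left out after the values were seen and the SD with it was 0.29, so a ratio common to all markers, as fewer microglia would give, was not shown. The median was −0.97 on FPKM as deposited, but the size factors of these libraries were 0.995 to 1.04, so this was no test of the scaling between libraries. Whether SKF lowers the number of microglia, the RNA in each or neither may be open, since groups have 2 libraries and cells were not counted, and Cx3cr1 lay 1.04 below the median ratio of the 7 (SE 0.33).

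The SKF response of the 283 SKF-induced genes was lower with JQ1, with a median difference of −0.08. Of 10000 random lists matched on mean expression, 0 percent had a median as low, which argues against a trend with expression level. Without SKF replicate 6 of experiment 1 the median was −0.03 and no longer passed, so that library could account for much of the pattern. A JQ1 effect on the response as a whole and the state of a single SKF library cannot be separated with 2 SKF libraries, so whether JQ1 alters the response as a whole stays open.

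Vps25 (chromosome 10, 89174684 to 89180160) was lower in the SKF plus iBD2 library, with a difference of −3.34. Its FPKM was 2.14 there and 25.3 to 28.6 in the other libraries of experiment 2, while the overlapping gene AABR07072184.1 had 19.0 FPKM there and at most 0.16 in the 22 other libraries. The summed coverage of both genes differed from that of the SKF libraries by 0.06 on the log2 scale. This is consistent with reads given to the other gene in that library, and argues against a lower level of the transcribed region. No biological explanation was tested.

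For the SKF by JQ1 difference at 60 min 1 gene passed, Sik1, at −0.49. For SKF by iBD2 2 genes passed, Vps25 and Sf3b6 (−0.85). At 24 h 6 genes passed, Fcgr3a (1.78), Cx3cr1 (1.42), Ltc4s (1.37), Clec4a1 (1.16), Igf1 (−0.76) and AABR07017159.1 (−1.27). The 4 positive ones lay under the pseudocount of 0.5 FPKM in both JQ1 groups, so that floor bears on their sign, and voom called none of the 4, with Cx3cr1 at −0.20. JQ1 and iBD2 effects differed in 127 genes and JQ1 effects at 24 h and 60 min in 5124.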

How the results depend on the processing

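All alternatives in this part were chosen before the data were examined. Of 15 counts, 13 stayed within 1.5 times on FPKM as deposited, 14 with a pseudocount of 0.1, 15 with a pseudocount of 1, 11 without a filter, 9 with each experiment alone and 13 with voom. The causes of the changes below were not tested. On FPKM as deposited iBD2 called 9 genes and SKF by iBD2 1. With a pseudocount of 0.1 SKF by JQ1 at 60 min called 0 genes. Without a filter it called 7, iBD2 with SKF 201, SKF by iBD2 145 and SKF by JQ1 at 24 h 27; genes near 0 enter these fits. With each experiment alone, which leaves fewer libraries, SKF in experiment 1 called 155, JQ1 at 60 min 394, SKF by JQ1 at 60 min 0, iBD2 with SKF 11, SKF at 24 h 85 and SKF by JQ1 at 24 h 1, and the iBD2 effect on SKF-induced genes was −0.028 and no longer passed. Voom called 4 genes for iBD2 and 5 for iBD2 with SKF, and Cx3cr1 turned to −0.20 in the SKF by JQ1 difference at 24 h.

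Whether the replicate numbers pair the libraries is not known here, and the main model did not pair them. In 15 pairs of groups within an experiment the correlation of deviations ran from −0.27 to 0.37, and 5 were above 0.1, which does not settle it. In 16 pairs between experiments 1 and 3, which share numbers, the correlation ran from −0.32 to 0.28, and 8 were above 0.1. With the replicate number as a block, SKF by JQ1 at 60 min called 0 genes and the other 14 counts stayed within 1.5 times. Of 649 named values the block ended the call of 14 and brought 2 past the threshold. The alternatives were run for 60 list calls, judged by an unadjusted camera p under 0.05 at the preset correlation. By that looser rule 59 of them held under every alternative that keeps all libraries, and none changed its side. For the named values the other alternatives ended 41 calls (as deposited), 18 and 3 (pseudocounts 0.1 and 1), 73 (no filter), 73 (alone) and 48 (voom).

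With 1 library left out, counts ran from 398 to 563 for SKF at 60 min, 158 to 242 in experiment 1, 204 to 361 in experiment 2, 316 to 640 for JQ1 at 60 min, 450 to 1026 with SKF, 0 to 3 for SKF by JQ1, 5 to 27 for iBD2, 3 to 6 with SKF, 1 to 4 for SKF by iBD2, 62 to 232 for SKF at 24 h, 6606 to 8024 for JQ1 at 24 h, 6521 to 7996 with SKF, 3 to 8 for SKF by JQ1 at 24 h, 65 to 145 for JQ1 minus iBD2 and 4148 to 5183 for JQ1 at 24 h minus 60 min. With the set chosen anew in each fit, the JQ1 effect on SKF-induced genes ran from −0.118 to 0.006 and the iBD2 effect from −0.03 to −0.008. The SKF by JQ1 difference of Fos ran from −0.17 to 0.45, of Arc from −0.17 to 0.83, of Nr4a1 from −0.19 to 0.54 and of Npas4 from −0.19 to 0.56, and the SKF by iBD2 difference of Fos from −0.29 to 0.02. List medians for the SKF by JQ1 difference at 60 min ran from −0.156 to −0.002 (striatal), −0.168 to 0.02 (synapse), −0.372 to 0.019 (mitochondrially encoded), −0.379 to 0.044 (cholesterol), −0.009 to 0.299 (astrocyte) and −0.073 to 0.34 (microglia), and at 24 h from −0.014 to 0.127 (ribosomal). Omissions ended 36 list calls, turned the direction given by camera for 7 others and ended 643 calls of named genes. The striatal list is among those turned, though its median kept its sign. Depth was 4.36 gigabases at the lowest, and its effect on low genes was not tested.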

Other observations

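The tests of hypotheses in this part were chosen after the result was seen. Genes of hypoxia and glycolysis moved with SKF at 24 h, as a list of 33 targets of the transcription factor HIF and glycolysis genes drawn up after Vegfa and Ldha had been seen. Of the 33, 18 rose, with a median of 0.33, where the middle 95% of 10000 random lists matched on expression ran from −0.03 to 0.04. Since the list holds Vegfa and Ldha, which had been seen in this same comparison, that is no test of it. Genes that rose include Vegfa (1.31 ± 0.08), the hexokinase gene Hk2 (0.69 ± 0.11), Ldha (0.64 ± 0.06) and the enolase gene Eno1 (0.42 ± 0.04). Egln3 (−0.11 ± 0.08), Adm (0.02 ± 0.18), Ndrg1 (0.00 ± 0.10) and Pfkfb4 (−0.22 ± 0.11) are among those that did not pass. A hypothesis is that SKF raises the genes of the list whether or not bromodomains are inhibited. In the separate libraries with JQ1, SKF plus JQ1 against JQ1, the median was 0.19 and 12 genes rose (middle 95% of random lists −0.05 to 0.03), with Vegfa at 1.06 ± 0.08 and Ldha at 0.61 ± 0.06. This is consistent with the hypothesis, and a difference in oxygen or cell density between dishes could give the same values and was not tested.

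The first 3 principal components of all libraries held 40.1, 29.2 and 8.2% of the variance, and the libraries with 24 h of JQ1 lay at 36.3 to 44.5 on the first. The Vegfa level in DMSO was 5.52 ± 0.456 FPKM in experiment 1, 10.1 ± 0.624 in experiment 2 and 5.94 ± 0.244 in experiment 3 (SD, n = 2). Txnip in DMSO stood at 19.0 ± 1.98, 5.22 ± 0.63 and 35.6 ± 1.62 FPKM.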
